A study of Vitis vinifera with 6 samples.

How the data were processed

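Total RNA from grape berry skin (Vitis vinifera, cultivar Pinot Noir) was hybridised to 6 one-colour NimbleGen expression arrays after Cy3 labelling by the array's maker, per the labels' protocols. Each array held 29549 probe sets, 1 per gene model of a grape genome annotation, and 29464 of these sets had 4 probes while 85 had fewer. A further row gave the average of 19605 random-sequence control probes and took no part in any test. The labels describe 3 samples kept dark for 1 hour and 3 samples under a UV-C lamp for 1 hour. They state that the replicates came from separate grape clusters.

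The deposited files per array give a mean intensity of the perfect-match probes of each set on a linear scale, in whole numbers, per the file headers. Their distributions differed between arrays, so the intensities were treated as not normalized. The same deposited files give the coefficient of variation of the probes in a set, a ratio of SD to mean, which was used to set the background limit and to describe probe agreement (median 0.414 over all sets and arrays). The authors also deposited a value table on a log10 scale for 23096 of the probe sets. Differences between any 2 of its columns were 0.301 times the difference in log2 intensity plus 1 constant per pair of arrays, with r = 1.00 across probe sets in all pairs. The table therefore held log10 intensities scaled by 1 factor per array and centred per probe set. Its baseline was not the mean or median of the 6 arrays or of the dark arrays and stays unknown. Its column medians were -0.00018, 0.0100 and 0.0072 for dark replicates 1, 2 and 3, and -0.0174, -0.0057 and -0.0121 for UV replicates 1, 2 and 3. The time between irradiation and sampling, image software, genome build and annotation version are not given in the sources used here.

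The intensities were background-corrected with normexp (offset 50), random-probe row included, and quantile-normalized on the log2 scale with limma 3.58.1 in R 4.3.3. UV was compared with dark by lmFit and eBayes over all 6 arrays with no covariate, two-sided, with Benjamini-Hochberg adjustment over the 29549 probe sets and a threshold of 0.05. Calls that also moved by over 1 on the log2 scale were counted separately. Every adjusted p printed for a probe set comes from that limma fit. A median polish over single probes, chosen before the data were examined, did not apply, since the files hold averages per probe set. The columns used carry no background flag, so, after the data had been seen, a limit was set per array at the mean plus 2 SD of the random-sequence probes. Brightness, unlike a count of reads, gives no depth, and the precision is limited by the number of arrays, 3 per group. The median standard error of a log2 change was 0.096. Simulated arrays took the dark levels and within-group variances of these 29549 probe sets, with 200 sets changed per run. The fit recovered 2% of the sets changed 1.25-fold, 39.6% at 1.5-fold, 70% at 2-fold and 93.6% at 4-fold. Of its calls, 5.53% were false. The Benjamini-Hochberg cutoff depends on how many sets change. These shares therefore do not give the recovery in the real comparison, which called 10818 sets.

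Gene names could not be assigned. The probe set identifiers carry a chromosome, an annotation block and a running number, and none of them matched any of the 29591 entries of the reference gene table (0 matched). The files do not pair identifiers with names. All 36 gene lists fixed at that time, which covered pathways, stress responses, transcription factors and markers of other tissues, therefore had 0 measured members, and neither they nor their planned set tests could be used. The rule for naming, fixed at the same time, allowed in that case 2 identifiers that rose and 2 that fell, those with the largest changes among called sets whose UV arrays all lay on one side of all dark arrays. A scan over gene order was added after the data had been seen, including the run of rises on chromosome 16, which had been looked up from outside knowledge of that chromosome before the scan was set up; the scan is therefore not independent evidence for that run. Gene models with a block and a running number (27504 in 1196 blocks) were ordered by number, windows of 10 neighbouring models with at least 8 calls in 1 direction were joined, and the result was trimmed to its outermost calls. The number of regions was set against 1000 shuffles of the calls over all ordered models. The running number was taken as the order along a block, which could not be checked because no coordinates were used. The remaining 2045 models carry no running number and stayed out of the scan. Shares per chromosome were compared with two-sided Fisher's exact tests, adjusted over the 33 chromosome labels, which treat probe sets as independent although neighbours were correlated.

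All 6 arrays carried the same slide identifier, with the dark arrays on neighbouring positions followed by the UV arrays, so position on the slide and group cannot be told apart. The replicate numbers recur in both groups and were not used as pairs. No 2 arrays shared more than 35 identical intensities. The values were also computed with median centring, the authors' value table, no background correction, a pseudocount of 16, 2 brightness filters, trended and robust variance models, a replicate block, array weights, a test against a 1.5-fold change and leaving out each array. Values without scaling, 2 further background treatments, lower bounds of fold on values without background correction and other window sizes were added after seeing the data.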

Results

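Transcript levels were measured in the skin of Pinot Noir grape berries, a cultivar of Vitis vinifera, to find the genes whose expression changed under ultraviolet-C light. Berry clusters stood for 1 hour at 50 cm from a lamp emitting at 253.7 nm, or beside it under a box that kept out the light. Each group had 3 arrays from separate clusters. Median probe-set intensity ranged from 8967 to 11200 units over the 6 arrays, and the random-sequence control probes averaged 736 to 882 units. Between 84.3% and 88.8% of the 29549 probe sets lay above the background limit on a single array, and 24460 (82.8%) did so on all 6. The identifiers on the array were not paired with gene names, so genes are described by identifier, chromosome and neighbourhood.

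The comparison of UV with dark asked which transcripts changed with 1 hour of irradiation. A large part of the skin transcriptome differed between the groups, which also lay on separate positions of the slide: 10818 probe sets (36.6%) passed the test, 4656 higher and 6162 lower after UV (limma, adjusted p under 0.05). Falls outnumbered rises over all calls, and rises outnumbered falls among changes of over 1 on the log2 scale. The median called rise was 0.67 on the log2 scale, or 1.59-fold, and the median called fall was -0.51, or 1.42-fold. Among changes of over 1 there were 1492 rises and 803 falls, against 1299 and 1152 without scaling between arrays. Among those over 2 there were 500 rises and 94 falls, against 356 and 52 without background correction. Changes of over 4 comprised 34 rises and 0 falls, against 12 and 0 without background correction and 24 and 1 without scaling. Among sets above background on all arrays they numbered 18 and 0. With the random-probe mean subtracted and low values raised to a fixed floor they numbered 57 and 4. Without UV replicate 2 they numbered 36 and 2. In 10812 of the called sets, all 3 UV arrays lay on one side of all 3 dark arrays, which follows largely from the calling itself. Such separation held for 54.4% of all sets, against 10% by chance. The first principal component held 82.0% of the variance. Arrays of the same group correlated at 0.989 or above, and arrays of different groups at 0.966 or below. Without scaling between arrays, the split of calls was 2939 higher and 6547 lower. The median change of all sets then moved from -0.05 to -0.17. With median centring the split was 4492 higher and 5107 lower. The size of the excess of falls over all calls therefore depended on the scaling. Without dark replicate 2 the falls numbered 3986.

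**Figure D1:**
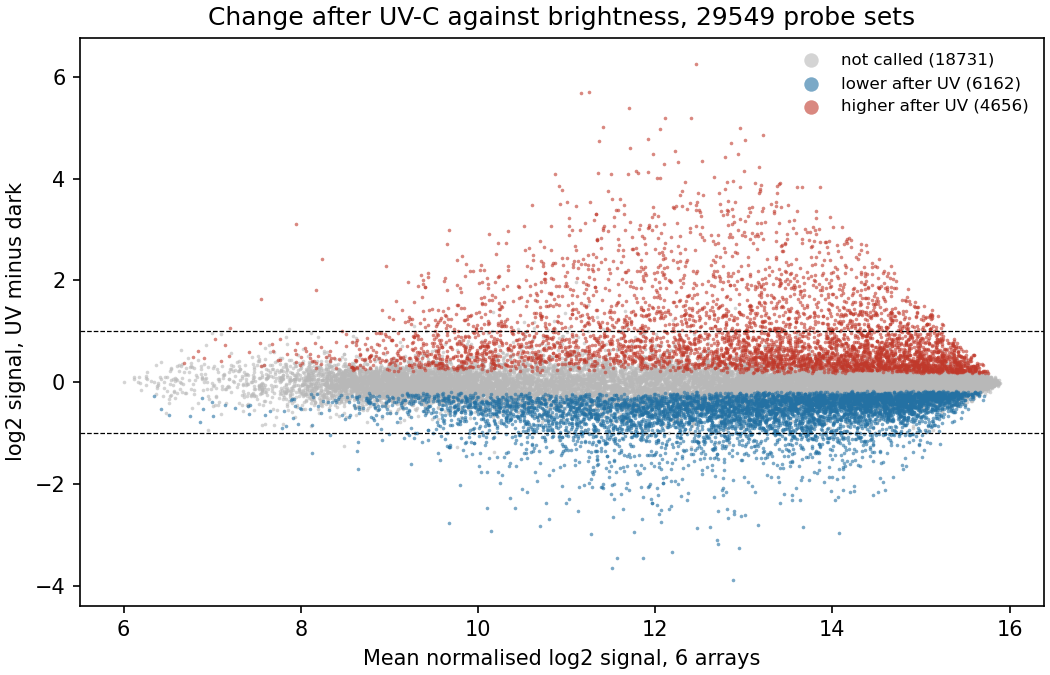
Change in normalised log2 signal, UV minus dark, against mean normalised log2 signal over 6 arrays, with 1 point per probe set. Red points are the 4656 sets called higher, blue points the 6162 called lower, grey points were not called, and dashed lines mark a change of 1; rises reach above 6 and no called fall passes -4 on these values, while 4 do with the random-probe mean subtracted.

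**Figure D2:**
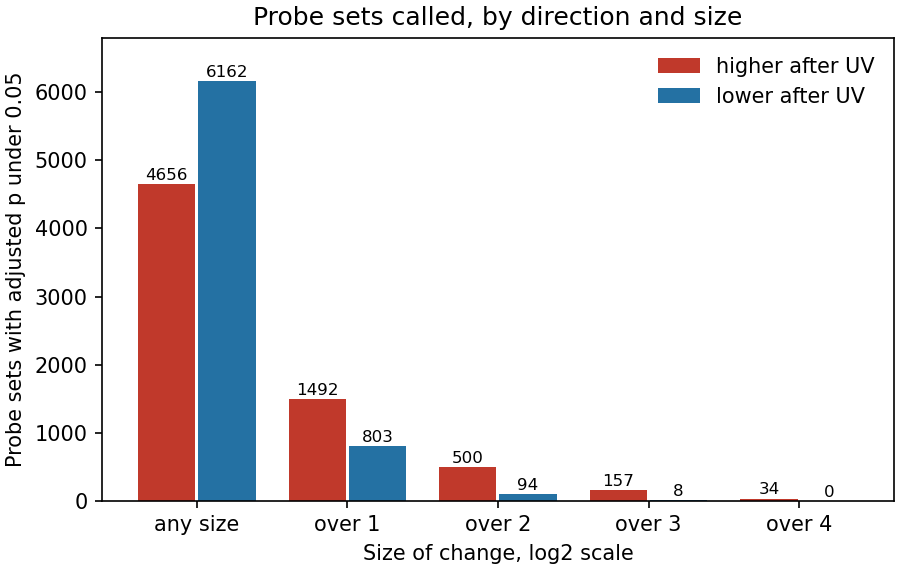
Number of probe sets with an adjusted p under 0.05 by size of the log2 change, in bars starting at 0, red for higher and blue for lower after UV. Falls outnumber rises over all sizes (6162 against 4656), and rises outnumber falls from a change of over 1 upwards (1492 against 803).

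The largest fitted rise was that of CHR6_JGVV9_102_T01, a gene model on chromosome 6. Its intensity was 1372 ± 512 units in the dark (SD, n = 3) and 49923 ± 7289 units after UV (SD, n = 3). The fitted log2 change was 6.26 (SE 0.36, adjusted p = 0.00014). Only 1 of the 3 dark arrays was above the background limit for this set, and the log2 change was 5.33 without background correction and 7.11 with the random-probe mean subtracted. The next largest, which ranked above it with the random-probe mean subtracted, was CHR15_JGVV24_20_T01 on chromosome 15, which was not above background on any dark array (964 ± 53.7 units, SD, n = 3) and reached 17703 ± 2159 units after UV (SD, n = 3). Its level rose at least 14-fold on values without background correction, measured against the lowest signals above background on the dark arrays. The adjusted p of the fit was 3.4e-05, and the size of its fitted change, 4.32 without background correction and 7.71 with the random-probe mean subtracted, was set by the background treatment. Among the 24460 sets above background on all 6 arrays, the largest rise was 5.19, on chromosome 7.

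The largest fitted fall was that of CHR3_JGVV38_312_T01 on chromosome 3, from 30234 ± 1406 units in the dark to 2524 ± 887 units after UV (SD, n = 3 each). Its log2 change was -3.89 (SE 0.26, adjusted p = 0.00022), a 14.8-fold drop, and it stayed above background on all 3 UV arrays. The log2 change of this set was -3.54 without background correction. CHR18_JGVV1_309_T01 on chromosome 18 dropped from 11558 ± 2238 to 1381 ± 498 units (SD, n = 3 each). Its log2 change was -3.65 (SE 0.29, adjusted p = 0.00042), with 1 of 3 UV arrays above the background limit. Without background correction its log2 change was -2.95. With the random-probe mean subtracted it was -4.19 against -4.09 for the set on chromosome 3, and the lowest value of any set was then -4.65, for another set on chromosome 3.

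A set of genes was at background in the dark and detected after UV. There were 151 called sets that were not above the limit on any dark array and above it on all UV arrays. On values without background correction their rise was at least 1.42-fold in the median, at least 2-fold for 38 of them and at least 8-fold for 6. The opposite course, from detected in the dark to background after UV, was taken by 84 called sets. On values without background correction their drop was at least 1.14-fold in the median and at least 2-fold for 4 of them, and 5 of them gave no bound above 1. Most calls, 9791, concerned genes above background on all 6 arrays, and 265 called sets were at background throughout.

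Changes were spread over the brightness range, with the largest numbers in the bins of middle mean brightness. That mean includes the UV arrays, so a set with a large change tends to land in a middle bin. The bins therefore do not show whether genes of middle level responded more. In the dimmest of 4 bins of probe sets, 230 rose and 110 fell by over 1. In the next bin these numbers were 643 and 403, and in the one above it 497 and 249. In the brightest bin they were 122 and 41, and the median size of a called change there was 0.40 against 0.68 in the bin next to the dimmest.

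Genes that changed by over 1 were found on all 19 chromosomes. Over the whole array 5.05% of probe sets rose and 2.72% fell by that much. Gene models that the annotation assigned to chromosome 18 without a position rose more often, with 39 of 234 (16.7%) rising by over 1 (Fisher's exact test, adjusted p = 1.6e-09). On chromosome 9, falls of over 1 were more frequent than elsewhere, at 54 of 1278 (4.23%), against 46 rises (Fisher's exact test, adjusted p = 0.048). On every other chromosome label the adjusted p of the same test was 0.17 or above for rises, and 0.29 or above for falls. The tests treated neighbouring probe sets as independent, which can make their p-values too small. The adjusted p for falls on chromosome 9 lay close to the threshold of 0.05.

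Neighbouring gene models, as ordered by running number, rose together in 23 regions on 14 chromosomes and on unplaced sequence. They fell together in 10 regions. The scan for such regions was added after the data had been seen. Shuffled calls gave at most 2 regions of rises and at most 6 of falls in 1000 shuffles. The longest region lay on chromosome 16, in annotation block 100, from gene model 12 to 54. Of its 39 probe sets, 36 were called higher, none was called lower and 3 were not called. The called rises ran from 0.30 to 3.54 on the log2 scale, 17 of them over 1 and 5 over 2. The median change of the region was 0.90 ± 0.064 (mean and SD over the 3 UV arrays, each against the dark mean). That SD leaves out the spread of the dark arrays. The median fitted change was 0.92, and ran from 0.82 without dark replicate 1 to 1.01 without dark replicate 3. The median intensity of the region went from 26437 units in the dark to 51541 units after UV. After UV, 23 of its members averaged over 50000 units, where the brightest set of any array stood at 63020. The other 78 models of the same block held 7 rises and 21 falls, with a median change of -0.09. Probe sequences were not used here, so signal shared between similar gene copies in the region could not be separated.

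**Figure D3:**
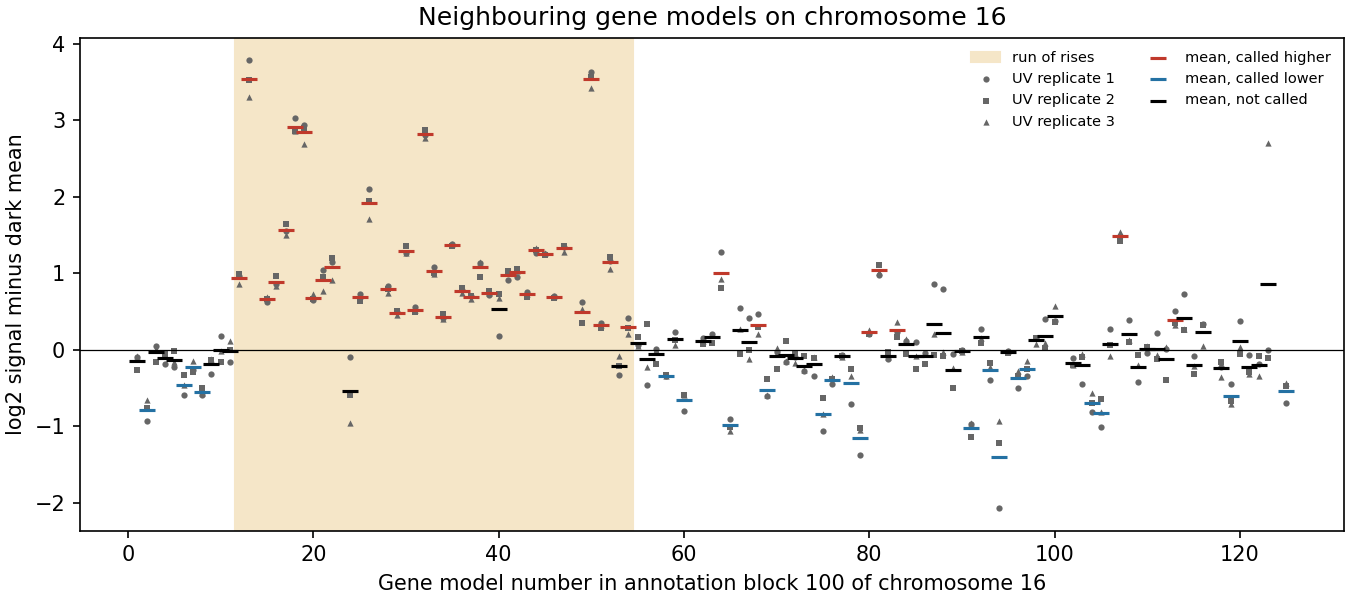
Log2 signal of each UV array minus the dark mean (grey symbols, 3 UV replicates) and their mean (bars, red if called higher, blue if called lower, black if not called) along the gene models of block 100 on chromosome 16. In the shaded region, models 12 to 54, 36 of 39 sets were called higher, while the rest of the block scatters around 0.

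The other regions of rises had fewer members, and since most started from dimmer levels their changes are not ranked against that of the long region. On chromosome 10, all 10 models from 61 to 70 of block 42 rose, 8 of them by over 1, with a median of 2.28. On chromosome 6, 8 of 9 models from 97 to 105 of block 9 rose, with a median of 3.26, and this region contained the set with the largest fitted rise, whose rank depended on the background treatment. On chromosome 18, 9 of 10 models from 27 to 36 of block 41 rose with a median of 2.01, and 1 fell. On chromosome 1, 12 of 14 models from 220 to 233 of block 10 rose with a median of 1.90. On chromosome 19, 16 of 18 models from 357 to 375 of block 14 rose with a median of 0.84. A further region on chromosome 16, models 63 to 75 of block 39, had 10 rises among 12 sets and a median of 0.56. The medians of the regions of falls lay between -0.33 and -0.80, and the one with the lowest median, models 328 to 342 of block 38 on chromosome 3, had 10 falls among 13 sets, 6 of them over 1. Which direction had more regions depended on the processing. There were 22 of rises and 27 of falls in the authors' value table, and 23 and 25 among sets above background on all arrays. Sets above the 25th percentile of brightness gave 23 and 27. Values without scaling gave 14 and 20, windows of 6 models 84 and 98, and the replicate number as a block 15 and 3. Shuffles were run for the main setting only, so these counts have no chance level of their own. Where fewer sets were tested, a window of 10 sets could span more gene models. The number of regions also depended on single arrays: there were 14 regions of rises without dark replicate 1 and 13 without dark replicate 2. Regions of falls numbered 2 without dark replicate 1, 2 without dark replicate 2, 4 without dark replicate 3 and 6 without UV replicate 3.

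The called sets moved farther in UV replicate 1 than in UV replicates 2 and 3. That the 3 arrays share a direction over these sets follows from the calling itself. The median change of the called rises was 0.77 in UV replicate 1, 0.62 in UV replicate 2 and 0.62 in UV replicate 3, each against the dark mean. For the called falls the medians were -0.58, -0.47 and -0.47. The mean correlation with the dark arrays was 0.945 for UV replicate 1, against 0.963 and 0.962 for UV replicates 2 and 3. Dark arrays correlated with each other at 0.994 to 0.995. Without UV replicate 1, 9784 sets were called, of which 9127 were among the original calls in the same direction.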

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

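The values without scaling, the limit to sets above background, the subtraction of the random-probe mean, the other window sizes, the lower bounds of fold without background correction, the counts of changes over 2 and over 4 and all counts of regions were chosen after the data had been seen. In none of the alternatives was one of the 10818 calls called in the opposite direction, although 9 changed sign without scaling and 15 with the random-probe mean subtracted, and the 4 named sets kept their direction and their calls wherever they were tested. Limiting the test to sets brighter than the median gave 6809 calls (2880 higher, 3929 lower; 619 and 291 over 1) and 13 regions of rises, with fewer sets tested. Testing against a 1.5-fold change instead of 0 gave 1688 calls, 1196 higher and 492 lower, 458 of the falls over 1, and 2 regions of rises and 0 of falls, since the bar is higher by construction. Without scaling between arrays 2939 sets were higher, with 14 regions of rises and 20 of falls; the cause was not tested. With the replicate number as a block, 8580 sets were called, 8204 of them original calls in the same direction, with 15 regions of rises and 3 of falls; the block uses up residual degrees of freedom, and it moved no count of calls by over 1.5 times. Deviations of same-numbered arrays correlated at -0.044, -0.059 and -0.033, and no array correlated best with its own number. Regions of falls numbered 6 with median centring, 27 with the authors' value table, 27 above the 25th percentile of brightness, 25 above background on all arrays, 18 with a variance trend and 19 with a robust trend; the cause was not tested. Windows of 6 with at least 5 calls gave 84 regions of rises and 98 of falls, and windows of 20 with at least 16 calls gave 2 and 0. Leaving out each array in turn gave 7464 to 9784 calls, 3471 to 4198 higher (1369 to 1551 over 1) and 3986 to 5645 lower (606 to 927 over 1), and 13 to 21 regions of rises and 2 to 8 of falls. The lowest count of falls, 3986, came without dark replicate 2. In the chromosome 16 run, 34 to 37 members were called with any 1 array left out, and 16 against a 1.5-fold change. The planned gene list tests were not run under any setting, and a slide block did not apply to 1 slide. Signal near background limits the fold of dim sets, and signal near the scanner's limit may limit that of bright ones.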

Other observations

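Gene models adjacent by running number changed alike well beyond the regions described. Over 26308 adjacent pairs the log2 changes correlated at r = 0.22 (across genes, which are not independent replicates), and the highest of 1000 shuffles gave 0.019. Outside the regions, 25875 pairs gave r = 0.18 against a highest shuffle of 0.021. Gene models also differed by annotation source. The tests of change below ran over all sets and did not take the share above background into account. Of the models with the prefix GSVIVT, 60.4% were above background on all arrays, against 85.0% of those with JGVV and 71.9% of those with PDVV. In Fisher's exact tests of each source against the others, adjusted over the 3 sources, GSVIVT models rose by over 1 less often (3.81%, adjusted p = 0.023), while the adjusted p for rises was 0.083 for JGVV (5.14%) and 0.73 for PDVV (5.25%). In the same tests, falls of over 1 were less frequent among PDVV models (1.36%, adjusted p = 0.0055) and more frequent among JGVV models (2.80%, adjusted p = 0.017). For GSVIVT models (2.45%) the adjusted p for falls was 0.48. JGVV models made up 26324 of the sets, so their test largely mirrors those of the other sources. The tests also treated probe sets as independent, although neighbours were correlated.

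The test of the scanner's limit was chosen after its result had been seen, the test of background in UV replicate 1 was set down after that array's gap over all probe sets had been seen, and the test by rank of the chromosome 10 region was added once an earlier test of the same hypothesis had left it undecided. Of the 10 splits of the 6 arrays, 1, the real one, gave 10818 calls in limma, and the highest of the others gave 0 (13939 sets at an unadjusted p under 0.05 in the real split, 275 to 734 in the others). Each of the other splits mixes UV and dark arrays, which puts the difference between UV and dark into the variance within groups. Their 0 calls are therefore no measure of chance, and the splits are too few for a share under 0.05.

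UV replicate 1 lay farther from the dark arrays than the other UV arrays. It had the lowest share of sets above background (84.3%), but background is argued against as the whole cause, because over the 14774 sets brighter than the median its mean correlation with the dark arrays was lower by 0.0823, against a spread of 0.0057 among the dark pairs. A larger amplitude of the same response may account for part of the gap: its difference from UV replicate 3 correlated at 0.3017 with the change in UV replicate 2, and its difference from UV replicate 2 at 0.3047 with the change in UV replicate 3, both barely above the bound of 0.3. The same measure between UV replicates 2 and 3 was 0.0048. Other faults of that array stay open, and no biological explanation was tested.

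Rises outnumbered falls among changes over 1. A background floor that hides falls of dim genes is argued against as the whole cause, since among 8289 sets of middle brightness the ratio of rises to falls over 1 was 1.828 (671 to 367). Scaling between arrays stays open. The ratio was 1.95 with median centring and 1.73 with the authors' value table, but 1.1276 without scaling, between the bounds that would have decided it. The response to UV also stays open, as untested.

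The run of rises on chromosome 16 may hold similar gene copies that share probe signal. Deviations of its 36 called members correlated at 0.7558 on average (0.624 over all 39). Random sets of rises of like brightness gave at most 0.343 in 1000 draws. Common regulation would give such a correlation too. In the other regions of rises, which had fewer called members, the same mean ran from -0.029 on chromosome 7 to 0.91 on chromosome 3. The value of the run is therefore not particular to it. Compression by the scanner's limit stays open. The rank correlation between dark level and change was -0.614 over all 39 members (-0.83 over the called ones, -0.42 over all other called rises). The dark level is itself part of the change, so a negative correlation is partly built in. The SD of levels after UV was 0.937 of that in the dark over all members and 0.478 over the called ones. Under 0.5 over all members was needed. That ratio over all members includes 2 sets below background on all arrays, neither of them called. A further hypothesis is that the run is the cluster of stilbene synthases, the enzymes that make resveratrol; the reference table (assembly ASM3070453v1) places VINST1 on chromosome 16 but links no array identifier to it. A related group was supposed on chromosome 10, where the scan found 1 region, but 14 of the 19 chromosomes held one, so that test decided nothing. By correlation with the run, the chromosome 10 region had rank 2 among 22 other regions (r = 0.63), a rank of 1 or 2 that chance gives in 9.09% of cases, which is weak evidence and names no gene.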
